A study of Homo sapiens with 6 samples.

How the data were processed

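AsPC-1 is an established human pancreatic cancer cell line. Per the labels, 3 samples carried a control lentivirus (control group) and 3 a lentivirus with a short hairpin RNA against TMPRSS4, a membrane-bound serine protease (shTMPRSS4 or knockdown group). Per the labels' protocols, total RNA was enriched for polyadenylated RNA with oligo(dT) beads, fragmented, reverse transcribed with random primers and sequenced on an Illumina HiSeq instrument. No step that marks the strand is described, so it is uncertain whether reads of a gene and of an antisense partner could be told apart. The submitters' processing notes name Bowtie 0.12.2 and the mouse builds mm8 and mm9, while all 753 rows of the table carry human Ensembl gene identifiers. The alignment reference that was used is therefore uncertain, and the counting tool, the annotation and the authors' statistical test are not given in the sources used here.

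The series was analysed from 1 table. Per the file headers it holds, for each gene and library, a whole-number read count and an FPKM value (fragments scaled by gene length and library depth), which the authors rounded to 2 decimals. It also holds the authors' mean FPKM per group, a log2 fold change, a p-value and a false discovery rate (FDR), with annotation terms. In the deposited table a group mean of 0 was replaced by 0.001, and the deposited log2 fold change is the log2 ratio of the group means, so for a gene at 0 it depends on that placeholder. Tested on the rows of the authors' deposited table, each had an absolute log2 fold change of at least 1 and an FDR of at most 0.0490, so the rows are a selection made on the outcome. In the authors' deposited table, the ratio of FDR to p of the lowest p-value was 15117, the number of genes the authors adjusted over. Genes outside the selection were not analysed here. TMPRSS4 itself was not analysed here, so no check of the knockdown was made.

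Sums of counts over selected genes are not library depths. The relative depth of each library was therefore taken from the ratio of count to FPKM, in which gene length cancels, as the median over 159 genes with at least 200 counts. Absolute depth came from 24 genes with 1 annotated transcript in GENCODE release 29, and the 5th to 95th percentile of these estimates for control replicate 1 was 57100000 to 57400000 reads. All 753 identifiers matched that annotation, which supplied chromosomes and coordinates (GRCh38). It need not be the annotation the authors used.

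The plan written before the data were examined had 2 branches, and the branch for a table of selected genes was followed. The authors' columns describe the list, and a test on the listed genes is descriptive, since a p-value on genes selected for a difference in the same libraries is not independent of that selection. The quasi-likelihood test of edgeR 4.0.16 (R 4.3.3) was run on the counts with its filter on low counts and robust estimation. TMM scaling, named in the plan for a table of all genes, was replaced by the recovered depth, because scaling over selected genes would force their average change towards 0. P-values were adjusted by the Benjamini-Hochberg method over the 705 listed genes that passed the filter, with a threshold of 0.05. They measure only the spread between these samples, since the labels do not say that the replicates were separate cultures. Fold changes are on the log2 scale with a standard error (SE) from the spread of log2 depth-scaled counts plus 0.5 over 3 against 3 libraries. Levels are the mean FPKM ± SD over 3 libraries of a group. Where all libraries of a group had 0 counts, a lower bound of the fold was computed against a floor of 3 counts over the group, which covers counting error only.

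The test was tried on simulated counts for 696 genes with the real means and depths. It recovered 41.1% of 56 genes changed 1.5-fold, 83.1% of 71 changed 2-fold and 100% of 70 changed 4-fold, and it called 2 of 499 unchanged genes. The simulated spread followed a smooth trend with level. Genes with uneven replicates, described below, were therefore not imitated, and the test can do less well on the real counts.

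Before the data were examined, 34 gene lists were fixed. For each, the listed members higher and lower were counted, and for the 9 lists with at least 4 listed members a two-sided Fisher's exact test set the split against that of the other listed genes, with Benjamini-Hochberg adjustment over those 9 lists. Such a test compares directions among selected genes and is no test of enrichment. Named genes followed a rule fixed at the same time. It took the 8 largest rises and the 8 largest falls in the authors' table among genes with a symbol, libraries that did not overlap between the groups and a mean of at least 5 FPKM in the higher group. It then took up to 4 members of each list with at least 3 passing members (lowest FDR), up to 2 of other lists, and 9 genes of ERK signalling, proliferation, apoptosis and cell adhesion, of which VIM was analysed here. The values of 1 gene that the rule names are not reported here. Genes named outside this rule are said to have been chosen after their values were seen.

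Reads shared between genes were estimated as the share of a gene's 31-mers that occur in transcripts of another gene in GENCODE release 29, with a threshold of 20%. Alternatives covered other scalings, filters, pseudocounts and tests (limma 3.58.1, DESeq2 1.42.0), stricter thresholds, the replicate number as a block and leaving out each library. The depth recovered from the table, TMM over the listed genes and adjustment over 15117 genes were added after the data were seen. The sample descriptions carry the code L3 for control replicate 3 and L4 for the other 5 libraries, whose meaning is not stated. It was treated as a possible batch, with L3 holding a single library. Pairs of replicates differed by more than counting noise, with a median chi-square 3.44 to 4.58 times its expectation, so no pair looked like 1 library deposited again, which does not show that the samples were separate cultures. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for the remaining steps.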

Results

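The series profiled RNA of AsPC-1 pancreatic cancer cells by sequencing in 3 control samples and 3 samples with lentiviral shTMPRSS4. Its title concerns proliferation, apoptosis and ERK1/2 signalling. The depth recovered from the table was 57200000, 37200000 and 30200000 reads in control replicates 1, 2 and 3. In the knockdown libraries it was 53300000, 50400000 and 46800000 reads. The genes analysed held between 1.23% and 1.40% of this depth. TMPRSS4 was not analysed here, so the knockdown itself was not checked and the name knockdown follows the labels alone.

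The comparison of knockdown with control asks which transcripts differ when TMPRSS4 is targeted. The authors' deposited table held 753 selected genes, of which 555 (73.7%) were higher in the knockdown libraries and 198 lower. In the authors' deposited table, the ratio of FDR to p of the last listed gene put at least 4954 genes at or below its FDR. The listed genes were 15.2% of that number, so their split describes the selection alone. The median log2 fold change in the authors' deposited table was 1.62 for the higher genes and -1.37 for the lower ones. Among genes with a mean of at least 5 FPKM in the higher group, SPINK4 and HEPACAM2 had the largest rises by log2 fold change, and NDUFA4L2, NDRG1 and TRIM31 the largest falls. Genes at low levels leaned more to the higher side. Of 248 genes with a mean under 0.5 FPKM over the 6 libraries 78.2% were higher, and of 71 genes with a mean of at least 20 FPKM 56.3% were higher.

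The edgeR quasi-likelihood test on the listed genes, which is not independent of their selection, tested 705 genes, and 699 passed at a Benjamini-Hochberg adjusted p under 0.05. Of these 517 (74.0%) were higher and 182 lower, and 695 changed at least 2-fold. No gene had a direction other than that in the authors' table. Without control replicate 3, the single library with the code L3, 705 of 723 tested genes passed among the remaining L4 libraries. L3 holds 1 library, so it gives no value of its own. When the scale was set by the listed genes alone, DESeq2 size factors gave 197 higher and 197 lower genes and TMM gave 167 and 191. Equal medians of FPKM gave 113 and 141 with limma. Upper-quartile scaling kept an excess of higher genes among those passing, 417 against 188 lower, as did equal sums of FPKM with limma, 277 against 128. Among genes that also changed at least 2-fold, upper-quartile scaling gave 223 higher and 188 lower. Equal sums gave 90 higher and 99 lower there, so that excess was not kept. The median log2 fold change of 1.29 moved by -1.17 with DESeq2 and by -1.21 with TMM, so directions below are relative to recovered depth.

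**Figure D1:**
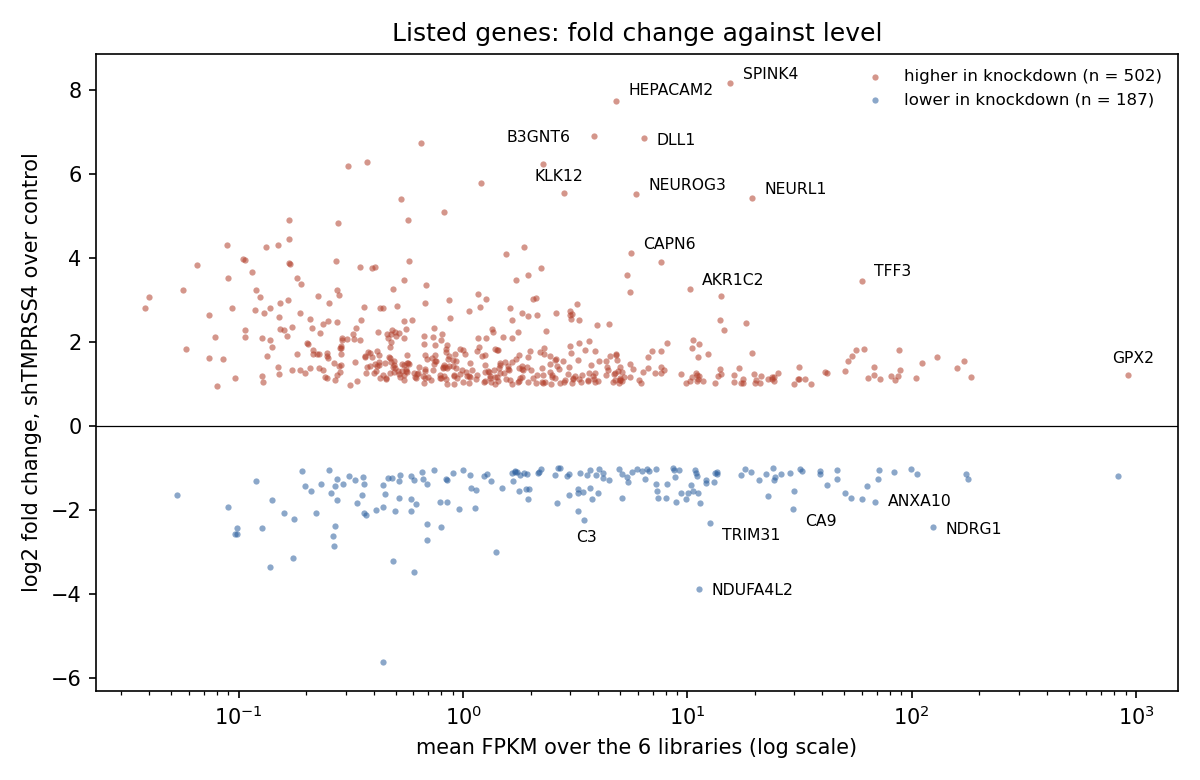
Log2 fold change of shTMPRSS4 over control (vertical axis) against the mean FPKM over the 6 libraries (horizontal log axis), 1 point per gene. The 502 higher and 187 lower genes are those fitted with counts in both groups, and genes below an absolute change of about 1 are absent because of the authors' selection.

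The 8 largest rises under the naming rule, which requires a mean of at least 5 FPKM in the higher group, began from control means under 1 FPKM. SPINK4 (ENSG00000122711, chromosome 9, 33218365 to 33248567), a Kazal-type inhibitor typical of goblet cells, rose from 0.0867 ± 0.0961 to 30.9 ± 0.766 FPKM (SD, n = 3 per group). Its log2 fold change was 8.16 ± 0.83 (SE), with an edgeR quasi-likelihood adjusted p of 3.24e-09. HEPACAM2 (ENSG00000188175, chromosome 7, 93188586 to 93226524) rose from 0.05 ± 0.0265 to 9.52 ± 1.11 FPKM, a log2 fold change of 7.73 ± 0.47. The Notch ligand DLL1 (ENSG00000198719, chromosome 6, 170282206 to 170306565) rose from 0.0967 ± 0.0737 to 12.8 ± 0.878 FPKM. B3GNT6, a glycosyltransferase of mucin O-glycan synthesis, rose from 0.06 ± 0.052 to 7.64 ± 0.289 FPKM. NEUROG3 (ENSG00000122859, chromosome 10, 69571698 to 69573238), the transcription factor that specifies endocrine progenitors, rose from 0.247 ± 0.00577 to 11.6 ± 0.831 FPKM, with a log2 fold change of 5.52 ± 0.06 and an edgeR adjusted p of 6.12e-10. NEURL1, an E3 ubiquitin ligase, rose from 0.86 ± 0.372 to 37.8 ± 0.085 FPKM. The kallikrein KLK12 and the calpain-family gene CAPN6 rose by 5.54 ± 1.52 and 4.12 ± 0.15 on the log2 scale. For SPINK4, HEPACAM2, DLL1, B3GNT6 and KLK12 the control counts summed to 6, 11, 26, 12 and 13 over 3 libraries, so the size of those folds is imprecise. NEUROG3 had 43 control counts over 3 libraries. Its small SE rests on close values at low counts and can understate the counting error.

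The 8 largest falls are those under the same rule, so each had a control mean of at least 5 FPKM. NDUFA4L2 (ENSG00000185633, chromosome 12, 57234903 to 57240715), a mitochondrial protein induced by hypoxia, fell from 21.2 ± 0.668 to 1.45 ± 0.292 FPKM (n = 3 per group). Its log2 fold change was -3.87 ± 0.18, with an edgeR quasi-likelihood adjusted p of 2.62e-09. NDRG1 (ENSG00000104419, chromosome 8, 133237171 to 133302022) fell from 209 ± 4.89 to 39.3 ± 3.84 FPKM, a log2 fold change of -2.41 ± 0.09. TRIM31, an E3 ubiquitin ligase, fell from 20.9 ± 0.105 to 4.23 ± 0.19 FPKM. The complement component C3 fell from 5.71 ± 0.28 to 1.23 ± 0.132 FPKM, and the transglutaminase TGM2 from 5.24 ± 0.458 to 1.29 ± 0.266 FPKM. CA9, a carbonic anhydrase induced by hypoxia, fell from 47.1 ± 2.66 to 12 ± 0.237 FPKM. The metalloprotease ADAM19 fell from 17.7 ± 0.596 to 5.02 ± 0.1 FPKM and FAM102B from 13.8 ± 1.24 to 3.95 ± 0.305 FPKM.

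**Figure D2:**
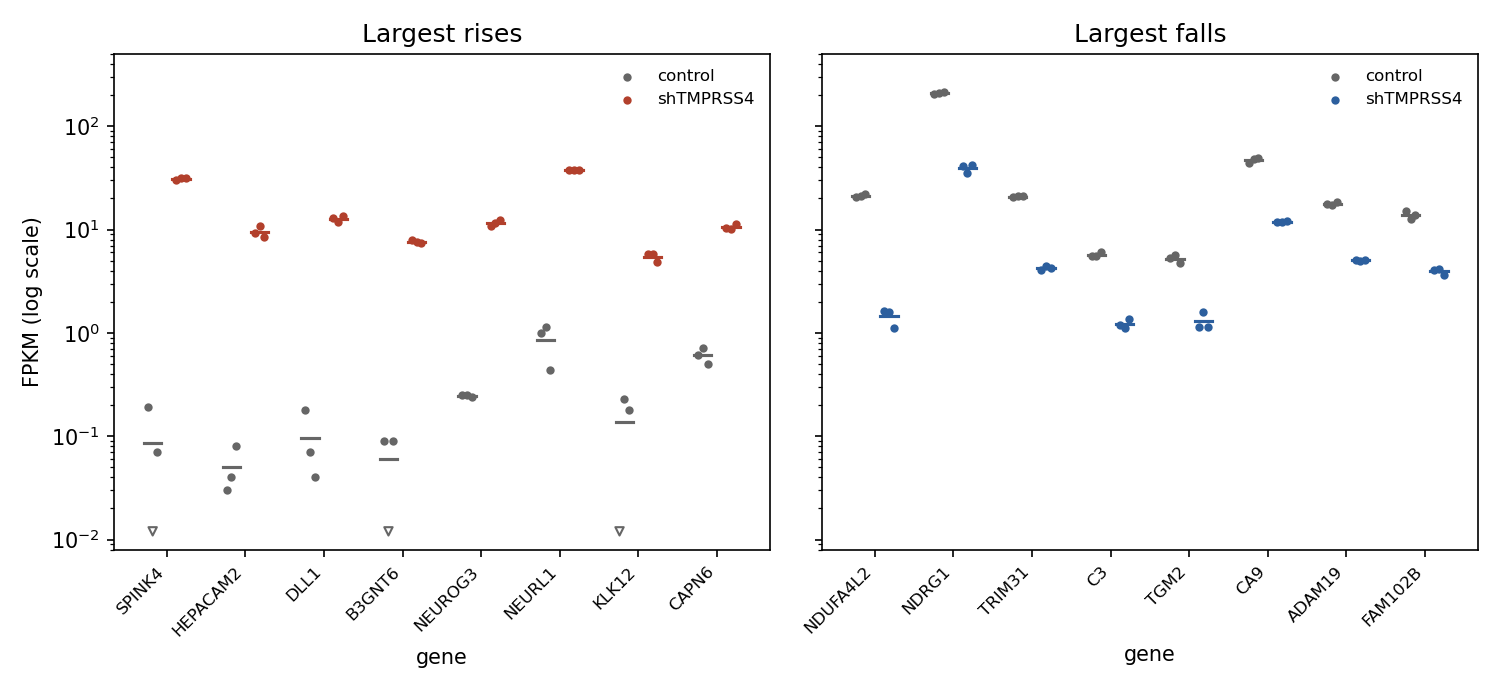
FPKM on a log axis for the 8 largest rises (left) and the 8 largest falls (right) among genes with a mean of at least 5 FPKM in the higher group, 1 point per library and a line at the mean of each group of 3. Open triangles stand for libraries at 0 FPKM and are drawn at 0.012. The 3 NDRG1 knockdown libraries lie near the mean of 39.3 against 209 in the controls.

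ERK signalling, the cell cycle and apoptosis had few or no members among the genes analysed. No member of 22 ERK pathway components, 33 G1/S and replication genes, 33 G2/M genes, 25 pro-apoptotic genes or 13 anti-apoptotic genes was among them, and genes outside the selection were not analysed here. Of 24 ERK target and feedback genes the ephrin receptor EPHA4 was listed, and it rose from 0.62 ± 0.0917 to 2.21 ± 0.03 FPKM. Of 24 CDK inhibitors and p53 targets 2 were listed and rose. BTG2, an antiproliferative gene, rose from 5.67 ± 0.576 to 30.9 ± 1.06 FPKM with a log2 fold change of 2.45 ± 0.09, and TP53INP1 rose from 0.227 ± 0.0603 to 0.72 ± 0.0872 FPKM. These members also passed when adjusted over the list alone, 1 of 1 and 2 of 2.

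Of the 9 lists with at least 4 listed members, 2 differed in direction from the other listed genes. Of 30 hypoxia and glycolysis genes 4 were listed. All 4 were lower, against 74.1% higher among the other listed genes (two-sided Fisher's exact test, Benjamini-Hochberg adjusted p = 0.0257). They were NDRG1, CA9, CA12, which fell from 99.3 ± 5.3 to 41.8 ± 3.4 FPKM, and ANGPTL4, which fell from 1.16 ± 0.292 to 0.23 ± 0.0693 FPKM. Of 32 serine proteases and inhibitors 6 were listed, 5 of them lower and 1 higher (two-sided Fisher's exact test, adjusted p = 0.0257). PLAU, the urokinase plasminogen activator, fell from 10.9 ± 0.926 to 3.76 ± 0.142 FPKM. KLK10 fell from 6.03 ± 0.273 to 1.99 ± 0.0458 FPKM and SERPINA3 from 9.74 ± 1.09 to 4.78 ± 0.763 FPKM. The trypsin inhibitor SPINK1 rose from 5.79 ± 0.753 to 18.9 ± 1.22 FPKM. KLK12 and SPINK4, which rose, were not in the fixed list, and the wider annotation term serine-type endopeptidase activity had 10 genes higher and 11 lower (Fisher's exact test, adjusted p = 0.188). Negative regulation of endopeptidase activity had 5 higher and 6 lower (adjusted Fisher p = 0.409). Both terms were read after the values were seen, with adjustment over 295 terms. The passing members adjusted over the list alone were 4 of 4 and 6 of 6. Without control replicate 2, or without shTMPRSS4 replicate 1, the serine protease list had 4 lower members and an adjusted Fisher p of 0.0533 or 0.0512. Among genes with a mean of at least 5 FPKM neither list kept the 4 members needed for the test.

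Of 34 genes of the classical subtype of pancreatic tumours 5 were listed, 4 lower and 1 higher. This split did not pass (Fisher's exact test, adjusted p = 0.0556). The same split passed without control replicate 1 (adjusted Fisher p = 0.0488), control replicate 3 (0.0463), shTMPRSS4 replicate 2 (0.0404) or shTMPRSS4 replicate 3 (0.0473). With the replicate number as a block it also passed (adjusted Fisher p = 0.0337). Apart from leaving out control replicate 1, these settings tested 8 or 6 lists instead of 9, which eases the adjustment. ANXA10 (ENSG00000109511, chromosome 4, 168092515 to 168187690), an annexin of gastric-type epithelium, fell from 107 ± 1.42 to 30.7 ± 0.818 FPKM and was 3.48-fold lower, with a log2 SE of 0.02. CEACAM6 fell from 12.3 ± 0.87 to 3.80 ± 0.125 FPKM and the aspartic protease CTSE from 18.1 ± 0.201 to 8.43 ± 0.0265 FPKM. The trefoil factor TFF3 rose from 10 ± 1.95 to 110 ± 1.02 FPKM. All 5 members passed adjusted over the list alone. Of the basal-like list 3 members were listed. SPRR1B rose from 9.43 ± 0.474 to 24.5 ± 0.47 FPKM, FAM83A fell from 0.39 ± 0.01 to 0.127 ± 0.0551 FPKM, and DHRS9 had 2.32 ± 0.909 in control and 1.08 ± 0.408 in knockdown libraries, which overlapped.

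Adhesion and inflammatory genes went both ways. In the integrin and matrix adhesion list 3 of 4 listed members were lower (Fisher's exact test, adjusted p = 0.130). COL17A1, a hemidesmosomal collagen, fell from 53.7 ± 1.46 to 24.4 ± 1.45 FPKM and COL4A1 from 0.167 ± 0.0751 to 0.03 ± 0.01 FPKM. COL4A2 rose from 2.25 ± 0.293 to 7.34 ± 0.426 FPKM. In the NF-kB and inflammatory list 3 of 5 were lower (Fisher's exact test, adjusted p = 0.210). The neutrophil chemokine CXCL8 fell from 82.5 ± 7.22 to 25.1 ± 2.35 FPKM and CSF2 from 7.68 ± 1.86 to 3.60 ± 0.497 FPKM, while IL18 rose from 2.20 ± 0.167 to 4.54 ± 0.314 FPKM and turned to the lower side under DESeq2 and TMM scaling over the listed genes. Of the interferon response list 2 members were higher and 2 lower (Fisher's exact test, adjusted p = 0.425). IFI6 rose from 8.35 ± 0.787 to 19.2 ± 1.84 FPKM and OAS2 from 0.63 ± 0.0954 to 1.44 ± 0.0751 FPKM, and both turned under TMM over the listed genes. CXCL10 fell from 0.317 ± 0.0808 to 0.0333 ± 0.0351 FPKM and IFI44 from 0.457 ± 0.177 to 0.07 ± 0.0608 FPKM. These 2 falls rest on few reads, 47 control and 6 knockdown counts for CXCL10 and 51 and 10 for IFI44. At an FDR under 0.001 the interferon list had 2 higher and 0 lower members. Of the metalloproteinase list 3 were higher and 2 lower (Fisher's exact test, adjusted p = 0.611). MMP1, interstitial collagenase, fell from 2.90 ± 0.265 to 1.04 ± 0.146 FPKM and MMP11 rose from 0.673 ± 0.111 to 1.83 ± 0.228 FPKM. MMP10 rose from 1.13 ± 0.233 to 2.47 ± 0.292 FPKM and turned under DESeq2 and TMM scaling over the listed genes. ADAMTS1 had 0 control counts and was at least 6.35-fold higher. All 4, 5 and 4 members of the adhesion, NF-kB and interferon lists passed adjusted over the list alone, and 3 of 5 of the metalloproteinase list did. ADAMTS1 of that list was removed by the filter on low counts and not tested.

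The 4 listed members of the list for MHC class I and antigen presentation were all class II pathway genes and all higher. With 73.6% of the other listed genes higher, 4 of 4 is the most extreme upward split and gives p = 0.578 (Fisher's exact test, adjusted p = 0.611), so the test could not pass in that direction. HLA-DMB, a peptide exchange chaperone, rose from 25.2 ± 1.35 to 88.0 ± 3.25 FPKM. HLA-DMA rose from 13.2 ± 1.15 to 27.0 ± 0.513 FPKM and turned to the lower side under DESeq2 and TMM scaling over the listed genes. HLA-DRA and HLA-DRB1 had 0 control counts and were at least 9.39-fold and 6.07-fold higher, at knockdown means of 0.18 and 0.117 FPKM. HLA-DRA and HLA-DRB1 were removed by the filter on low counts and not tested, and the other 2 of the 4 members passed adjusted over the list alone. The NRF2 and glutathione list had 4 of 4 members higher, where the same limit holds (Fisher's exact test, adjusted p = 0.611), and of these 3 passed adjusted over the list alone. The aldo-keto reductase AKR1C2 rose from 1.95 ± 0.0961 to 18.5 ± 0.579 FPKM, AKR1C1 from 23.9 ± 0.812 to 58.1 ± 0.319 FPKM and AKR1C3 from 65.0 ± 2.36 to 145 ± 6.19 FPKM. AKR1C3 turned under DESeq2 and TMM scaling over the listed genes, and GPX2 under TMM. GPX2, a glutathione peroxidase of the gut epithelium, had 559 ± 26.8 FPKM in control and 547, 1674 and 1646 FPKM in knockdown replicates 1, 2 and 3. It did not pass the edgeR test (adjusted p = 0.0671).

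Lists with fewer than 4 listed members were not tested for direction. All 3 listed WNT genes rose, namely SP5 from 4.52 ± 0.528 to 16.4 ± 0.874 FPKM, the stem cell receptor LGR5 from 2.24 ± 0.431 to 7.41 ± 0.616 FPKM and NOTUM from 0.17 ± 0.0557 to 0.753 ± 0.133 FPKM. All 3 listed Notch genes rose, namely DLL1, DLL4 from 1.29 ± 0.0737 to 3.83 ± 0.293 FPKM and HES4 from 11.4 ± 1.89 to 23.4 ± 6.46 FPKM, although HES4 turned under DESeq2, TMM and equal-median scaling over the listed genes. The mesenchymal genes VIM and ACTA2 rose from 3.17 ± 0.623 to 8.22 ± 0.596 FPKM and from 4.21 ± 0.541 to 10.1 ± 1.15 FPKM. AXL, also the 1 listed YAP target, fell from 0.43 ± 0.08 to 0.19 ± 0.0361 FPKM. Of the epithelial junction list CLDN18 fell from 0.143 ± 0.0416 to 0.0367 ± 0.00577 FPKM. In the TGF-beta list ID2 had 42.9, 46.6 and 13.8 FPKM in the controls and 14.1 ± 0.572 in the knockdown libraries, and did not pass the edgeR test (adjusted p = 0.0580). FGFR2 rose from 6.45 ± 0.598 to 15.4 ± 0.755 FPKM and IGFBP2 fell from 7.81 ± 0.19 to 3.08 ± 0.871 FPKM. The linker histone gene H1F0 fell from 251 ± 9.78 to 105 ± 1.18 FPKM, while H2AFX rose from 87.3 ± 1.98 to 254 ± 9.97 FPKM. The members that passed adjusted over the list alone were 3 of 3 for WNT, Notch, mesenchymal and basal-like lists, 2 of 2 for growth factors and histones, 1 of 1 for YAP targets and epithelial junctions, and 0 of 1 for TGF-beta.

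Few members of the lists of other cell types fixed in advance were among the listed genes. Lists made after the values were seen, described below, had more, with 16 goblet and secretory progenitor and 11 enteroendocrine genes, all higher. Because those lists were made with the values known, their larger number and common direction are no independent evidence. The acinar elastase CELA3A rose from 0.293 ± 0.0416 to 3.59 ± 0.65 FPKM, and the hormone gene GCG had 0 control counts and was at least 6.62-fold higher, at a knockdown mean of 0.15 FPKM. The fibroblast gene FAP rose from 0.513 ± 0.0987 to 1.8 ± 0.218 FPKM and the endothelial gene PECAM1 fell from 0.523 ± 0.14 to 0.197 ± 0.0451 FPKM. Adjusted over the list alone, 1 of 2 acinar and endocrine genes and 2 of 2 fibroblast and endothelial genes passed. GCG was removed by the filter on low counts and not tested. No immune cell marker of 17 was among the genes analysed. The same holds for 32 genes of the unfolded protein response, 26 of cholesterol and fatty acid synthesis, 20 metallothionein and heat shock genes, 24 of autophagy and lysosomes, 13 mitochondrially encoded transcripts and 41 ribosomal proteins. At least 20% of the 31-mers of AKR1C1, AKR1C2, CELA3A, CA9, PLAU, VIM, ACTA2, SERPINA3 and HLA-DRB1 occur in other genes, so their levels depend on how the authors assigned shared reads. Exons of another annotated gene on the opposite strand cover 38.5% of CA9, 31.1% of PLAU, 24.4% of VIM and 30.1% of ACTA2, and on the same strand 43.2% of CELA3A and 31.8% of SERPINA3.

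**Figure D3:**
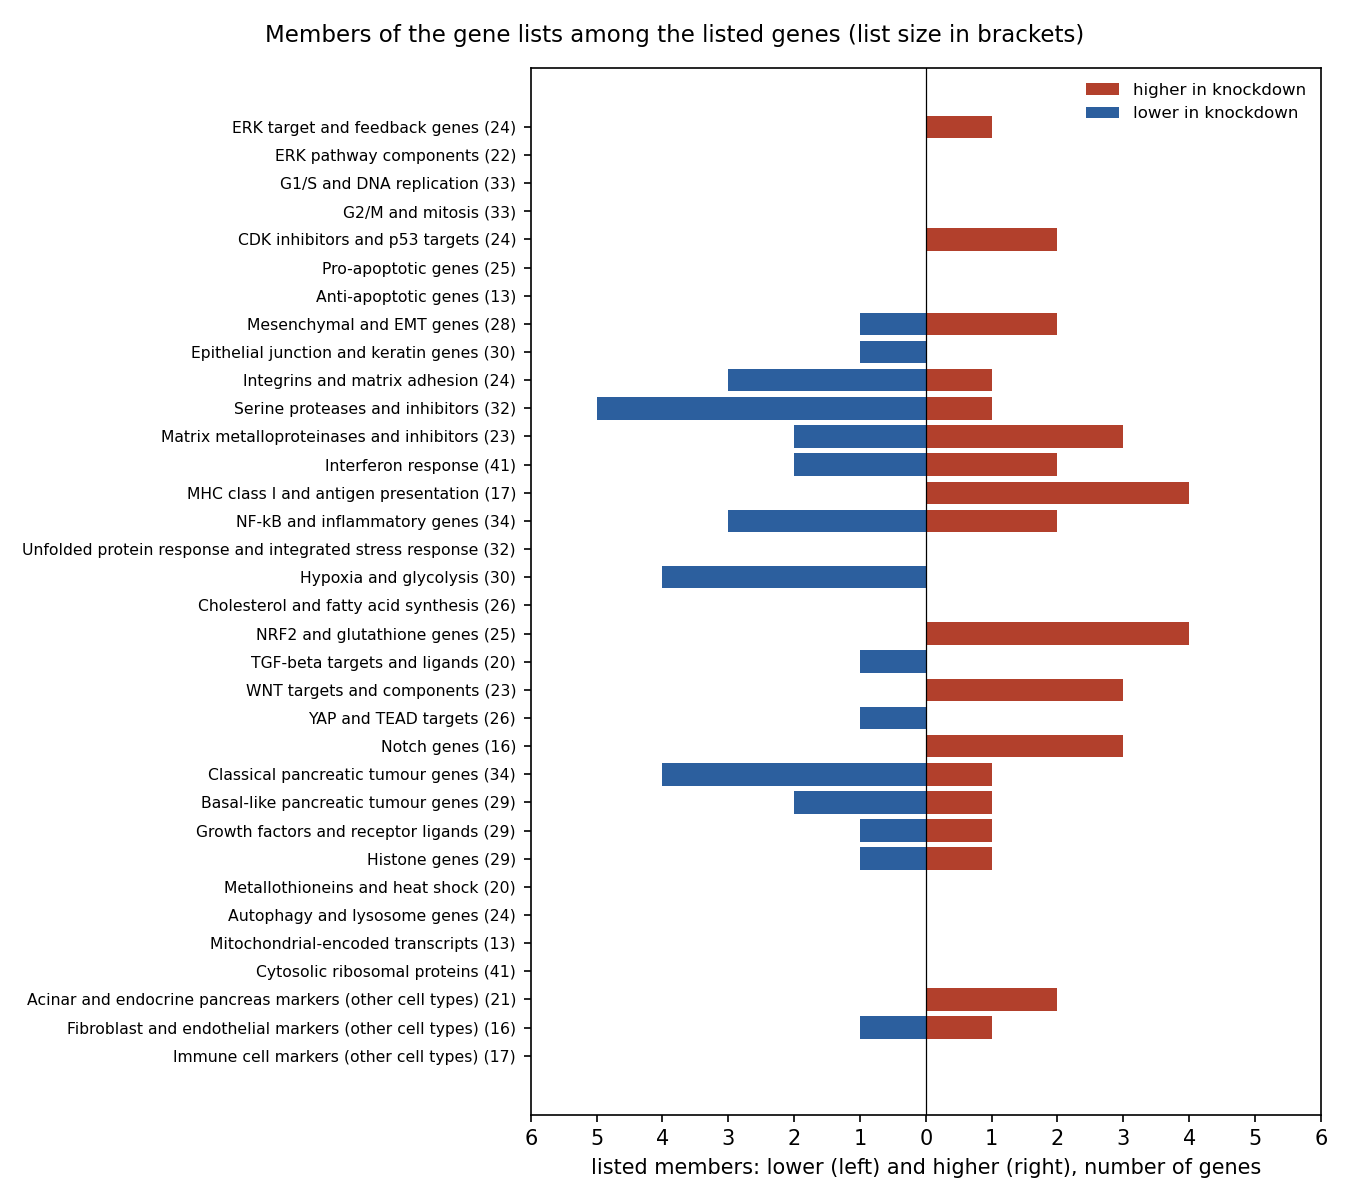
Number of members of each of the 34 lists that were among the listed genes, higher in the knockdown libraries to the right of 0 and lower to the left, with the size of each list in brackets. Hypoxia and glycolysis (4 lower) and serine proteases (5 lower, 1 higher) have adjusted Fisher p-values of 0.0257. Under TMM over the listed genes the directions of 8 list members differ from those drawn.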

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

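TMM over the listed genes, DESeq2 with recovered depth, adjustment over 15117 genes and restriction to genes with counts in each group or passing the edgeR test were chosen after the data were seen, and the other alternatives before. Against 699 passing genes, scaling over the listed genes gave 394 with DESeq2 size factors and 358 with TMM, sets that need not lie within the 699. With limma on log2(FPKM + 1), which gave 430 unscaled, equal sums gave 405 and equal medians 254. DESeq2 size factors, TMM and equal medians force the centre of selected genes towards 0 by construction. Equal sums left a median log2 fold change of 0.68 over 412 genes. Upper-quartile scaling shifted the median by -0.66 and gave 605. Limma on FPKM tested fewer genes after its filter on low values and called 432 with a pseudocount of 0.1 and 171 at a mean FPKM of at least 5. Against 695 genes changed at least 2-fold, the same settings gave 341 for DESeq2, 306 for TMM, 411 for upper quartile, 189 for equal sums, 169 for equal medians, 228 and 408 for the pseudocounts 1 and 0.1, 139 at a mean of at least 5, and 231 with limma and no filter, where a pseudocount of 1 shrinks the fold of low genes. DESeq2 with recovered depth called 752, limma-voom 692, adjustment over 15117 genes 580, and leaving out 1 library 697 to 705, with 663 to 674 at 2-fold.

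Under DESeq2 size factors over the listed genes the log2 fold changes of AKR1C3, HLA-DMA, IL18, HES4 and MMP10 turned to -0.016, -0.14, -0.13, -0.14 and -0.032. Under TMM they were -0.053, -0.17, -0.16, -0.18 and -0.073, and those of IFI6, OAS2 and GPX2 were -0.014, -0.0093 and -0.00073. HES4 was at -0.018 with equal medians. These genes rose by close to the shift that the scaling removes. Of 1313 refits of 69 named genes 1256 kept direction and side of the threshold, 34 fell below it and 9 passed only then.

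Of the 753 selected genes 243 had an absolute log2 fold change of at least 2, 483 an FDR under 0.001 in the authors' deposited table and 388 a mean FPKM of at least 1, each a smaller set by construction. Leaving out 1 library left 708 to 727 at an absolute log2 fold change of at least 1. The number of lists passing was 2, and 0 among genes with a mean of at least 5 FPKM, where the hypoxia and serine protease lists kept 3 members each. Leaving out 1 library gave 1 to 3 lists. It was 1 without control replicate 2 and 1 without shTMPRSS4 replicate 1, where a serine protease member left the selection (adjusted p = 0.0533 and 0.0512, Fisher's exact test). The classical list joined at an FDR under 0.001, under the block and among genes passing the edgeR test. Its adjusted p there was 0.0275 to 0.0357 (Fisher's exact test), against 0.0556. It also joined without control replicate 1 or 3 or shTMPRSS4 replicate 2 or 3, at 0.0404 to 0.0488 (Fisher's exact test). The split of this list stayed at 4 lower and 1 higher. At an FDR under 0.001, under the block and among genes passing the edgeR test, 4, 6 and 6 lists were tested instead of 9. Without control replicate 3 or shTMPRSS4 replicate 2 or 3 it was 8. Fewer tested lists ease the adjustment.

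With the replicate number as a block 682 genes passed, 676 of them at 2-fold, and 3 lists. Same-numbered samples deviated with correlations of -0.03, 0.06 and -0.10 across 385 genes, and 0 of 3 control samples correlated best with its own number, so the numbers were not taken as pairs. Camera, fry and all alternatives for TMPRSS4 were not run, the former because the list was selected and the latter because TMPRSS4 was not analysed here. Depth limits folds of genes with few control counts, 49 of which had 0 counts in all 3 controls.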

Other observations

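All tests in this part, with their gene lists and the genes named, were chosen after the values had been seen. Of 23 goblet and secretory progenitor genes 16 were listed and all 16 were higher. Of these 15 passed the edgeR test, and the other was removed by its filter on low counts and not tested. The split from the other listed genes did not pass the correction (two-sided Fisher's exact test, Benjamini-Hochberg adjusted p = 0.0564 over 6 such lists). ATOH1, the master regulator of secretory fate, rose from 0.813 ± 0.162 to 9.99 ± 0.225 FPKM (SD, n = 3 per group), the mucus protein FCGBP from 4.12 ± 0.386 to 17.2 ± 0.382 FPKM and HES6 from 62.5 ± 4.81 to 197 ± 12.7 FPKM. The transcription factor gene GFI1 rose from 0.0467 ± 0.0115 to 0.647 ± 0.1 FPKM. All 11 listed enteroendocrine genes of 29 were higher (Fisher's exact test, adjusted p = 0.152). PROX1 rose from 0.437 ± 0.140 to 3.67 ± 0.332 FPKM and MYT1 from 0.830 ± 0.101 to 2.70 ± 0.0473 FPKM, while PAX4 and RFX6 had 0 control counts and reached 1.64 ± 0.0751 and 0.510 ± 0.0173 FPKM. TMM scaling over the listed genes turned MUC4 and CREB3L1 of these lists to the lower side, and DESeq2 size factors MUC4.

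In the other lists of this kind each listed member was also higher. That is the most extreme upward split, and with most other listed genes higher it gave unadjusted p from 0.0762 to 0.578, so Fisher's exact test could not pass upward for these lists or the enteroendocrine list. With Benjamini-Hochberg adjustment, these were 6 of 15 intestinal stem cell genes (adjusted p = 0.419), 4 of 15 tuft cell genes (0.578), 11 of 23 motile cilium genes (0.152) and 7 of 16 cornified envelope genes (0.299). EPHB3 rose from 7.84 ± 0.337 to 20 ± 0.374 FPKM, ALOX5 from 11.7 ± 0.219 to 28.0 ± 0.312 FPKM and SPRR1A from 2.88 ± 1.03 to 25.3 ± 2.08 FPKM. Of the 31-mers of SPRR1A 26.25% occur in other genes, so its level depends on how the authors assigned shared reads. SPEF2 of the cilium list and CNFN of the envelope list turned under DESeq2 and TMM scaling over the listed genes. The filter of limma on low FPKM values kept 2 of the 11 cilium genes. The pepsinogens PGA3, PGA4 and PGA5 had 0 control counts and reached 0.783 to 1.70 FPKM, but 57.2% to 78.7% of their 31-mers occur in other genes. Among 295 annotation terms in the authors' table with at least 8 listed genes, 5 differed in direction from the other listed genes. External side of plasma membrane had 14 of 20 genes lower (Fisher's exact test, adjusted p = 0.0125), positive regulation of cell migration 10 of 14, and regulation of cell proliferation and leukocyte migration 8 of 10 each (adjusted p = 0.0327 each). Extracellular space had 62 genes higher and 44 lower (Fisher's exact test, adjusted p = 0.0327).

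Summed over the 27 goblet and enteroendocrine members, control libraries held 170, 158 and 165 FPKM and knockdown libraries 653, 627 and 644, and 7 members, with HES6, SOX4, CREB3L1 and TFF3 the most abundant, had a control mean of at least 1 FPKM. Lower control depth is argued against, since the median member would have given 1292 control counts at its knockdown level, where counting error is small, and control replicate 1, deeper than each knockdown library, held 170 FPKM. A small number of other cells in the knockdown cultures may give the same rise. The summed level varied by 2.05% (CV) between knockdown libraries, which an even admixture before the samples were divided would also give, so that and a change within the AsPC-1 cells cannot be told apart. A response to shTMPRSS4 stays a hypothesis, and effects of the hairpin other than on TMPRSS4 were not tested.

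Clustered protocadherin genes on chromosome 5 were picked because most were on 1 side, so the unadjusted test of their split (two-sided Fisher's exact test, p = 0.0139) is no independent evidence. All 12 listed beta genes (141094578 to 141249365, GRCh38) were higher, with log2 fold changes from 1.08 to 3.01, and all 9 listed gamma genes (141355025 to 141512979) from 1.16 to 3.95, while PCDHAC2 of the alpha cluster was lower at -1.09. The median level was 1.69 FPKM for the beta genes and 0.387 FPKM for the gamma genes. The filter of limma on low FPKM values kept 9 of the 12 beta genes and 0 of the 9 gamma genes. DESeq2 and TMM scaling over the listed genes turned PCDHB2, PCDHB3, PCDHB15 and PCDHGA4. Reads shared between paralogs may add to the pattern, since a median of 40.4% of their 31-mers occur in other genes, and at that share a common change and reads lent by a few members cannot be told apart.

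Among 461 listed genes with a group mean of at least 100 counts, 45 had replicates of a group that differed at least 1.8-fold, including MAPK14, PLEKHB1, GPX2 and ID2. MAPK14, the p38 alpha kinase, had 45.8, 16.9 and 41.7 FPKM in control replicates 1, 2 and 3. These genes had more annotated transcripts than the others, a median of 9 against 5 (permutation test, p = 0.0027). That was predicted if read assignment among transcripts made the replicates uneven. The counts are per gene, though, and a gene total need not change when reads move among its own transcripts. Of the genes named, MAPK14 and PLEKHB1 had 10 and 22 transcripts, and GPX2 and ID2 had 5 and 4. The difference therefore does not decide whether read assignment made the replicates uneven. At least 20% of 31-mers were shared in 12 of the 45 and in 69 of the other 416 genes (Fisher's exact test, p = 0.1001), which leaves shared reads open. The design names no biological difference between replicates of a group, so no biological explanation was tested.

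Of the 10 splits of the 6 libraries into groups of 3, 1 gave as many passing genes as the real split, which was the real split itself with 699, and the highest of the others gave 2. With 10 splits no share under 0.05 can be reached, and the genes had been selected on the real split.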
